A study of Drosophila melanogaster with 8 samples.

How the data were processed

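Eye discs of larvae of the third instar were collected in pools of 30 to 50 per sample at a culture temperature of 25 °C, per the labels' protocols and the series' design text. Per the same sources, RNA was extracted with Trizol, depleted of ribosomal RNA and made into strand-specific libraries, and single-end reads of 50 bp were produced. The design text names a HiSeq2000 and the extraction protocol a HiScanSQ as the sequencer, and which was used for each library is not given in the sources used here. Per the labels, the 8 libraries are 2 biological replicates of each of 4 stocks. The p-values of single genes and of the rotation test below are set against the spread between such samples. Those of camera compare a list's members with other genes under a correlation between members, preset unless said to be estimated. Fisher exact p-values take genes as units. Genes are not independent replicates, so very small p-values of these kinds do not measure how well a difference repeats between samples.

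The deposited values are raw counts of reads per gene in each library, with no normalization by the authors, per the labels. Per the submitters' processing notes, CASAVA 1.8.2, FastQC, TopHat2, Subread and featureCounts were used. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping and antisense genes could therefore not be told apart with certainty, and near-identical copies such as histone, Hsp70 and some snoRNA genes may share reads. The tables hold 15682 FlyBase gene identifiers, of which 15002 matched a symbol and a position in the Ensembl 115 annotation of BDGP6.54 and 680 did not.

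Total counts per library ran from 11929158 to 19670470. Counting intervals are exact 95% intervals, and a fold against a stock with no read was taken against a floor of 3 counts over the group. Intervals and floors cover counting error only, since they use counts summed over a stock's libraries and leave out the spread between replicates. Reads made by PCR are not independent molecules, so the counting error itself may be larger than given.

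The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors from 0.9711 to 1.036), the filter of filterByExpr, which kept 11068 genes and left out 4614, a model with a mean per stock over all 8 libraries, the robust quasi-likelihood test with 4 residual degrees of freedom, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 20.6% and the median prior degrees of freedom 3.03. All 6 pairs of stocks were compared. With 2 libraries per stock no test of other splits of the samples was made, and each stock's mean ± SD rests on n = 2.

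Named genes are, per comparison, the 10 largest rises and 10 largest falls among called genes with a fold change of at least 2, a mean of at least 5 CPM in the higher stock and no overlap of libraries between stocks; the locus genes, Cbl, the 4 apoptosis inducers rpr, hid, grim and skl, and w; genes called the same way in both RMCE stocks against both references; and per gene list up to 4 called members with the smallest adjusted p, or else up to 2 by mean level.

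The 34 gene lists, of signalling, development, cell cycle, stress, metabolism and markers of other cells, held 773 members, of which 741 matched an identifier, 29 did not and 3 were left out as ambiguous. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it. Fry tests whether the members move one way on balance and does not compare them with other genes. A gene list was also tested with its members' p-values adjusted over the list alone.

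The steps were tested on simulated data drawn from the means and library sizes of these samples, with 100 genes changed 2-fold and 100 changed 4-fold among 11068. A further list of genes changed less was counted neither as recovered nor as false. Each comparison had a single draw in which genes varied independently. Transcripts that move together in a library, such as those of other cells, were not simulated, so the rates below may not hold for these data. For the knockout stock against Canton S 53% of the 2-fold and 82% of the 4-fold changes were recovered, with 6.58% of calls false. For the other comparisons, in the order RMCE-1 and RMCE-2 against Canton S, RMCE-1 and RMCE-2 against the knockout stock, and RMCE-2 against RMCE-1, recovery was 53, 55, 55, 49 and 55% at 2-fold and 85, 79, 74, 77 and 77% at 4-fold, and 7.84, 7.48, 8.84, 7.8 and 7.43% of calls were false, above the nominal 5%.

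Counts of called genes and the values of named genes were recomputed with DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals alone, no filter on low counts, a filter of 50 counts in 2 libraries, the replicate number as a block and only the groups compared. They were also recomputed without each library in turn, where the lone library left in a stock is assumed to vary like the other groups. The list tests were recomputed with DESeq2 size factors, library totals, no filter, the block and each library left out. Fits without Canton S replicate 1 and RMCE-1 replicate 2 together (genes and lists) and without structural RNA (ribosomal, 7SL and mitochondrial) and unnamed genes (genes alone) were chosen after the data were seen, as were the filter settings for named genes. Planned tests of genes with seed matches to miR-998 or miR-11 need transcript sequences, which were not used here, and were not run. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, exact tests and figures.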

Results

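RNA was measured in eye discs, the larval epithelial sacs that give rise to the adult eye and antenna, dissected from Drosophila melanogaster larvae of the third instar. The 8 libraries came from 4 stocks with 2 biological replicates each, per the labels: the wild-type strain Canton S, a stock labelled mir-11 KO(w-) (called the knockout stock here), and a pair of stocks labelled RMCE-1 and RMCE-2 for the mir-11 and mir-998 region. RMCE commonly stands for recombinase-mediated cassette exchange, a way to place a chosen sequence at a fixed genomic site, and the sequences placed in these stocks are not given in the sources used here. Per the series' design text, wild type was set against miR-998 left unchecked, and which of the stocks that describes is not stated. Each sample held 30 to 50 discs, and total RNA depleted of ribosomal RNA was sequenced. Total counts per library were 19670470 and 19157088 in Canton S, 18290314 and 16656252 in the knockout stock, 16071008 and 11929158 in RMCE-1, and 13095980 and 17643039 in RMCE-2. Levels are given as CPM, the counts scaled to a common library total, as mean ± SD over the 2 libraries of a stock. Unless said otherwise, a gene or list is called where its Benjamini-Hochberg adjusted p is under 0.05, from the edgeR quasi-likelihood test for genes and from limma's camera for gene lists. For every named gene that was called, both libraries of one stock lay above both libraries of the other.

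Libraries of one stock resembled each other unequally. Among genes at 5 CPM or more, the median absolute log2 difference between the replicates was 0.09 in Canton S, 0.07 in the knockout stock, 0.14 in RMCE-1 and 0.12 in RMCE-2, and 52, 38, 125 and 41 genes differed by over 4-fold. As a check for a library deposited more than once, the chi-square per degree of freedom between replicates was 28.9, 10.01, 53.5 and 22.1, and the replicates were counted as separate libraries. The Hsp70 genes, which encode the heat-inducible chaperone and whose near-identical copies can share reads, summed to 10 and 18 CPM in Canton S, 18.2 and 17.5 CPM in the knockout stock, 20.1 and 4170 CPM in RMCE-1, and 723 and 91.8 CPM in RMCE-2. Transcripts of larval fat body, a storage organ, summed to 1100 and 759 CPM, 383 and 193 CPM, 164 and 9280 CPM, and 573 and 2360 CPM over the same libraries. The storage protein transcript Lsp2 alone reached 2570 CPM in RMCE-1 replicate 2 against 13.1 CPM in replicate 1. Salivary gland transcripts, among them the glue genes and the transcription factor gene CrebA, summed to 2400 and 1580 CPM in Canton S, 742 and 569 CPM in the knockout stock, 201 and 4810 CPM in RMCE-1, and 214 and 217 CPM in RMCE-2. CrebA alone made up 154, 175 and 177 CPM of the sums in RMCE-1 replicate 1 and both RMCE-2 libraries. Canton S replicate 1 held the most gut transcripts (350 CPM against 71.3 to 138 CPM in the others) and the most testis transcripts (51.4 CPM against 11.9 to 16.9 CPM). Fits without Canton S replicate 1 and RMCE-1 replicate 2, the pair of libraries that stood apart, were added after the data were seen.

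**Figure D1:**
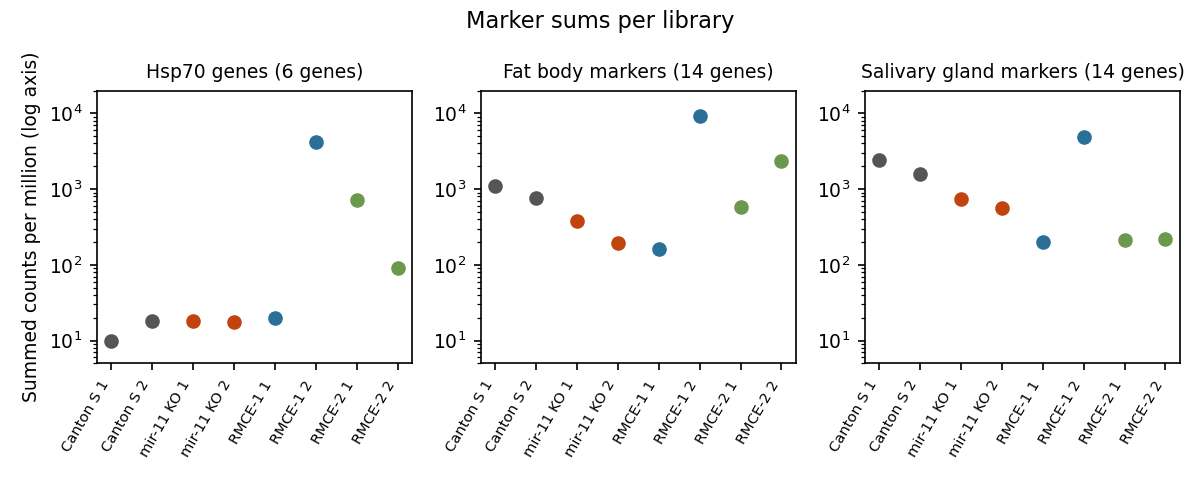
Summed CPM (log axis) of Hsp70 genes, fat body markers and salivary gland markers, 1 point per library, with the stocks along the horizontal axis. RMCE-1 replicate 2 holds 4170 CPM of Hsp70 and 9280 CPM of fat body transcripts, against 20.1 and 164 CPM in RMCE-1 replicate 1.

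The edited region lies in E2f1 (FBgn0011766), which encodes the cell cycle transcription factor and spans 3R 21620304 to 21660871 on the minus strand in BDGP6.54 (Ensembl release 115, which may not be the build used for counting). The mir-11 hairpin (FBgn0262434, 21622497 to 21622571) and the mir-998 hairpin (FBgn0262405, 21621879 to 21622021) both sit in the last intron of all 6 annotated E2f1 transcripts. Reads assigned to mir-11 numbered 2 and 0 in Canton S, 0 and 0 in the knockout stock, 0 and 0 in RMCE-1, and 0 and 1 in RMCE-2, too few to check the knockout label. At this depth a loss of mir-11 was not detectable, and libraries of long RNA count host intron and precursor rather than the mature microRNA. Reads assigned to mir-998 numbered 16 and 20, 12 and 13, 14 and 9, and 18 and 31, or 0.932 ± 0.202, 0.707 ± 0.0921, 0.835 ± 0.0889 and 1.56 ± 0.247 CPM, and no pair of stocks was called over all genes (edgeR adjusted p from 0.255 to 0.896). E2f1 itself stood at 215 ± 7.39 CPM in Canton S, 229 ± 1.79 CPM in the knockout stock, 205 ± 5.3 CPM in RMCE-1 and 194 ± 6.81 CPM in RMCE-2. Its largest difference, RMCE-2 against the knockout stock, was a log2 fold change of -0.24 (SE 0.06, edgeR adjusted p = 0.151). Adjusted over the list alone, with E2f1 and mir-998 as its 2 tested members, E2f1 was called lower and mir-998 higher (log2 fold change 1.14, SE 0.37) in RMCE-2 than in the knockout stock (edgeR adjusted p = 0.00827 and 0.0176), and neither was called in the other 5 comparisons. Both of these calls were lost without RMCE-2 replicate 2 (log2 fold change -0.208 and 0.96). That of mir-998 was also lost without knockout replicate 1 (1.01) and with DESeq2 (adjusted p = 0.101). In other settings E2f1 gained list-alone calls. With library totals alone it was called lower in RMCE-1 than in the knockout stock (edgeR adjusted p = 0.027). With the filter of 50 counts, where E2f1 was the only member tested, it was called lower there (0.0302) and in RMCE-2 than in Canton S (0.0299).

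Genes reported as targets of these microRNAs were called in no comparison. The pro-apoptotic genes rpr, hid, grim and skl, are reported as miR-11 targets. hid, the most abundant of them, stood at 52.2 ± 4.28 CPM in Canton S, 47.6 ± 2.09 CPM in the knockout stock, 61.2 ± 14.7 CPM in RMCE-1 and 55.2 ± 5.05 CPM in RMCE-2. rpr stood at 8.33 ± 0.613, 7.44 ± 1.28, 14.5 ± 10.2 and 9.11 ± 2.95 CPM in the same order, and its counts in RMCE-1 were 113 and 253. Cbl, a negative regulator of EGFR signalling reported as a miR-998 target, stood at 57.8 ± 2.58, 58.8 ± 2.56, 54.0 ± 1.84 and 62.2 ± 2.38 CPM (edgeR adjusted p from 0.209 to 0.862). The list of 5 reported targets was not called by camera in any comparison. The eye colour gene w, which encodes a pigment precursor transporter and commonly marks transgenes, stood at 39.1 ± 6.44 CPM in Canton S, 0.570 ± 0.201 CPM in the knockout stock, 3.75 ± 0.687 CPM in RMCE-1 and 2.06 ± 0.232 CPM in RMCE-2. Against Canton S, w had log2 fold changes of -6.09 (SE 0.27), -3.37 (SE 0.22) and -4.25 (SE 0.24) in the knockout stock, RMCE-1 and RMCE-2 (edgeR adjusted p = 0.000515, 0.0014 and 0.00106).

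The knockout stock was compared with Canton S for differences that go with the labelled loss of mir-11. Any other difference between these stocks, such as strain background, is confounded with that loss here. Of the genes named for the knockout stock in this and the next paragraphs, ppk13, snoRNA:Psi18S-1377a and AttA were also called higher in both RMCE stocks against Canton S. CG3984, CG42779 and Dronc were also called lower in both. Others were called in a single RMCE stock, such as Tektin-C, higher in RMCE-2. Tektin-C, which encodes an axonemal filament protein, stood at 27.8 ± 5.16 CPM in the knockout stock and 0.226 ± 0.168 CPM in Canton S (log2 fold change 6.87, SE 0.55). The ion channel gene ppk13 rose from 0.175 ± 0.171 to 14.1 ± 0.83 CPM. A guide RNA for rRNA pseudouridylation, snoRNA:Psi18S-1377a, rose from 2.16 ± 0.749 to 50.2 ± 0.628 CPM, and CG32373 from 2.33 ± 0.478 to 21.2 ± 0.0224 CPM. Copies named snoRNA:Psi18S-1377b, snoRNA:Psi18S-1377c and snoRNA:Psi18S-1377e were called lower in both RMCE stocks against Canton S (edgeR adjusted p at most 0.00153, 0.0116 and 0.00403). Such copies may share reads, so the rise of a single copy need not be a rise of the guide RNA as a whole. CG3984 was lower, at 0.140 ± 0.0295 CPM against 18.2 ± 0.447 CPM (log2 fold change -6.94, SE 0.45). The edgeR adjusted p was 0.00392 for Tektin-C, 0.00214 for ppk13, 0.000515 for the snoRNA, 0.000917 for CG32373 and 0.000996 for CG3984, and these 5 genes were called in every left-out-library fit and every other setting. Transcripts of CG42779 were absent from both knockout libraries, at least 379-fold lower than the 31.7 ± 10.8 CPM of Canton S (edgeR adjusted p = 0.0135). That call was lost without knockout replicate 1 or 2 (adjusted p up to 0.0676) and with DESeq2 (0.145).

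Ecdysone-response genes, which follow the steroid pulses that time larval stages, were lower in the knockout stock than in Canton S, with 7 of 20 members lower and none higher (10 lower adjusted over the list alone; camera adjusted p = 1.24e-06, or 0.532 with an estimated correlation). The nuclear receptor gene Hr3 stood at 26.9 ± 6.97 CPM against 105 ± 11.2 CPM in Canton S (log2 fold change -1.96, SE 0.21, edgeR adjusted p = 0.00669). ImpE1, an ecdysone-inducible gene of imaginal discs, stood at 232 ± 2.4 CPM against 435 ± 1.48 CPM, and the transporter gene E23 at 23.8 ± 1.56 CPM against 48.6 ± 9.56 CPM. These calls of ImpE1 and E23 were lost without either knockout replicate, at edgeR adjusted p up to 0.0676 and 0.0948. Salivary gland transcripts, with none of 14 members called singly or adjusted over the list alone, lay lower as a list (camera adjusted p = 0.0245, or 0.893 with an estimated correlation), and that call was lost without Canton S replicate 1 (0.0673) or knockout replicate 2 (0.213).

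Mitosis genes lay higher as a list in the knockout stock than in Canton S, with 5 of 25 members called higher and none lower (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.87e-06, or 0.893 with an estimated correlation; fry adjusted p = 0.075). Among them the spindle protein gene feo stood at 120 ± 4.84 CPM against 85.5 ± 1.02 CPM, the condensin gene barr at 84.3 ± 2.73 against 62.1 ± 1.28 CPM, and fzy, an activator of the anaphase-promoting complex, at 81.0 ± 1.5 against 62.5 ± 0.698 CPM. The mitotic phosphatase gene stg, held in the E2F and replication list, stood at 284 ± 7.17 against 197 ± 14.2 CPM (log2 fold change 0.53, SE 0.08, edgeR adjusted p = 0.0148). Calls of feo, barr and fzy were each lost without any 1 of the Canton S or knockout libraries (edgeR adjusted p up to 0.108, 0.148 and 0.205), and that of stg without Canton S replicate 1 or either knockout replicate (up to 0.128). Without the pair of libraries that stood apart, feo and barr were at 0.0607 and fzy at 0.0759. The caspase gene Dronc fell from 140.3 ± 1.79 to 83.1 ± 0.5 CPM (log2 fold change -0.76, SE 0.08, edgeR adjusted p = 0.00438), a call lost without knockout replicate 1 or 2 (up to 0.0617).

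Camera called 5 further lists between the knockout stock and Canton S, none of them with an estimated correlation (adjusted p of 0.955 for the ribosomal proteins and 0.893 for the others). Antimicrobial and other immune effectors lay higher (2 of 20 members called higher, 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0253), with AttA at 25.4 ± 6.3 CPM against 3.87 ± 1.44 CPM. Dosage compensation genes lay higher (1 of 6 members, 4 adjusted over the list alone; 0.0151), as did retinal determination genes (0 of 12, 3 adjusted over the list alone; 0.0375) and cytosolic ribosomal protein genes (0 of 78, 0 adjusted over the list alone; 0.0253). The dosage compensation genes summed to 1163 and 1659 CPM in Canton S and 2264 and 2372 CPM in the knockout stock. The sex of the larvae is not given in the sources used here, and a difference in the share of males was not tested. Hemocyte markers lay lower as a list (1 of 18 higher and 1 lower, 1 and 4 adjusted over the list alone; 0.00231). The peroxidasin gene Pxn stood at 83.2 ± 9.77 CPM against 152 ± 33.5 CPM and NimC1, which was higher, at 9.83 ± 0.13 against 3.49 ± 1.45 CPM. Without Canton S replicate 1 the retinal and ribosomal lists were not called (camera adjusted p = 0.158 and 0.891), nor were the immune and hemocyte lists without Canton S replicate 2 (0.248 and 0.133). The retinal list also lost its call without knockout replicate 2 (0.213) or RMCE-2 replicate 2 (0.0501), and the ribosomal list without knockout replicate 1 (0.0806) or 2 (0.0628), and without the pair that stood apart they were at 0.121 and 0.516. AttA was lost without any 1 of the Canton S or knockout libraries (edgeR adjusted p up to 0.11). Pxn lost its call without Canton S replicate 2 or any knockout or RMCE-2 library (up to 0.203) or with only the 4 libraries compared (0.101). NimC1 lost its call without Canton S replicate 1 or any knockout or RMCE-2 library (up to 0.187).

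In all, the edgeR quasi-likelihood test called 526 of 11068 genes between the knockout stock and Canton S, 262 higher and 264 lower, of which 194 differed by at least 2-fold. Higher genes made up 49.8% of calls, against 38.4% with DESeq2, 34.7% without Canton S replicate 1 and 32.3% without the pair that stood apart. The count was 219 without Canton S replicate 1, 177 without replicate 2, 80 without knockout replicate 1 and 65 without replicate 2, and 1139 with only these 4 libraries in the fit. Camera called 8 of the lists, or 5 without knockout replicate 2, against 0 with an estimated correlation, and the rotation test fry called 2, the ecdysone list and the eye pigment list with w in it (fry adjusted p = 0.0166 and 0.0123).

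**Figure D2:**
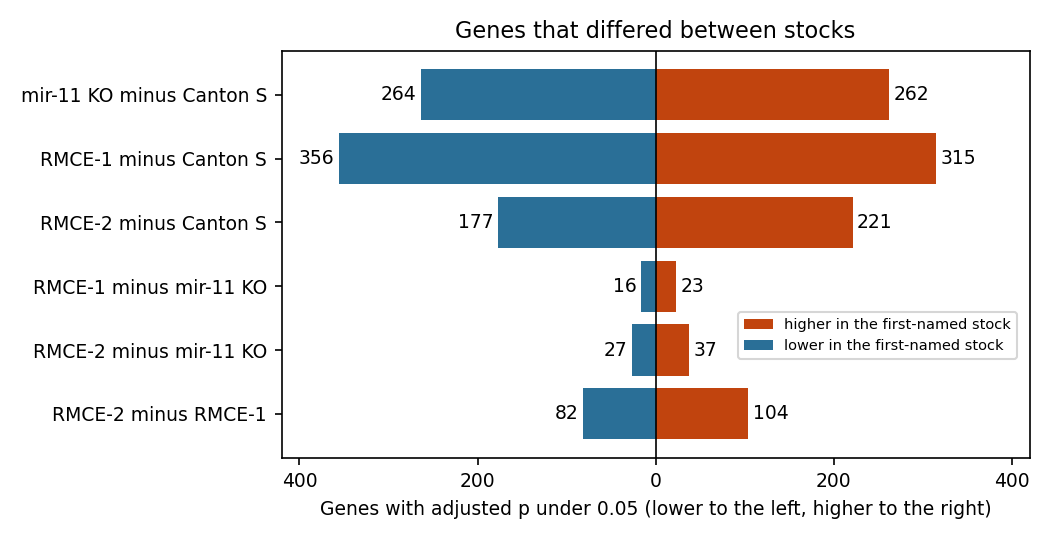
Genes called in each of the 6 comparisons (horizontal axis, number of genes with an edgeR adjusted p under 0.05), with bars to the right for genes higher and to the left for genes lower in the first-named stock. Each stock against Canton S gave 398 to 671 genes, and each RMCE stock against the knockout stock 39 and 64.

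RMCE-1 was compared with Canton S as one reading of the design text, in which wild type is set against unchecked miR-998. Gr64a, a gustatory receptor gene for sugars, stood at 13.5 ± 0.38 CPM in RMCE-1 against 1 read over both Canton S libraries (ratio 525, counting interval 93.6 to 20800). The sugar transporter gene sut2 rose from 1.15 ± 0.185 to 12.4 ± 0.0619 CPM (log2 fold change 3.42, SE 0.17), and snoRNA:Psi28S-1837a from 1.87 ± 0.695 to 29.9 ± 2.22 CPM. Map205, which encodes a microtubule-associated protein, fell from 459.5 ± 16.8 to 40.5 ± 4.8 CPM (log2 fold change -3.50, SE 0.10). The edgeR adjusted p was 0.0044 for Gr64a, 0.00064 for sut2, 0.000874 for the snoRNA and 4.38e-05 for Map205, and the 4 genes were called in every left-out-library fit and every other setting. CG3984 (log2 fold change -4.37, SE 0.37, edgeR adjusted p = 0.00264) and the hairpin RNA hpRNA:CR32207 (-3.74, SE 0.38, 0.00403) were lower with the same stability.

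Ecdysone-response genes were lower in RMCE-1 too, with 6 of 20 members lower and 1 higher relative to Canton S (7 and 1 adjusted over the list alone; camera adjusted p = 0.00395, or 0.99 with an estimated correlation). Eip75B, a nuclear receptor gene, stood at 182 ± 7.34 against 288 ± 17.6 CPM (log2 fold change -0.66, SE 0.10, edgeR adjusted p = 0.0137), and Hr4 at 62.8 ± 3.5 against 149 ± 8.47 CPM (-1.25, SE 0.18, 0.0148). The call of Eip75B was lost without Canton S replicate 2 (edgeR adjusted p = 0.0764), and that of Hr4 without any 1 of the Canton S or RMCE-1 libraries (up to 0.0777). Without the pair that stood apart they were at 0.102 and 0.176.

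**Figure D3:**
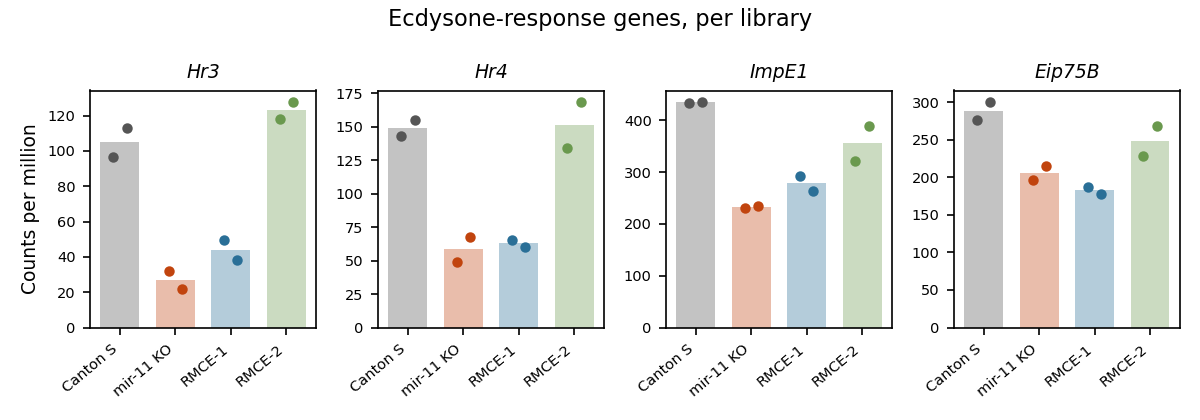
Levels of the ecdysone-response genes Hr3, Hr4, ImpE1 and Eip75B in CPM (vertical axis) by stock, with bars for the mean of 2 libraries and points for each library. Hr3 stood at 105 CPM in Canton S and 123 CPM in RMCE-2, against 26.9 CPM in the knockout stock and 44.0 CPM in RMCE-1.

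Among Notch targets, 2 of the 9 Enhancer of split genes in the list rose in RMCE-1 relative to Canton S. E(spl)mdelta-HLH rose from 44.4 ± 2.18 to 67.4 ± 3.76 CPM (log2 fold change 0.60, SE 0.07, edgeR adjusted p = 0.00581). E(spl)m3-HLH rose from 39.1 ± 2.87 to 57.4 ± 0.88 CPM (0.55, SE 0.09, 0.0188). In the same list N and mam were lower, giving 2 of 18 members higher and 2 lower (6 and 3 adjusted over the list alone) with no call of the list (camera adjusted p = 0.569). Markers of the antennal disc moved both ways. The transcription factor gene bab2 fell from 134 ± 1.09 to 83.7 ± 3.24 CPM (log2 fold change -0.68, SE 0.07, edgeR adjusted p = 0.00403) and ct fell from 129 ± 7.22 to 84.1 ± 5.04 CPM (-0.62, SE 0.07, 0.0057). In contrast dan, which acts in eye and antenna, rose from 66.8 ± 0.183 to 87.6 ± 2.81 CPM (0.39, SE 0.06, 0.013). E(spl)m3-HLH lost its call without Canton S replicate 1 (edgeR adjusted p = 0.108) and dan without either Canton S replicate (up to 0.0808). N lost its call without any 1 library except RMCE-2 replicate 1 (up to 0.145), and mam without any 1 of the 8 libraries (up to 0.193). With only the 4 libraries compared, E(spl)mdelta-HLH, E(spl)m3-HLH, N, mam, dan, ct and repo were at edgeR adjusted p = 0.0568, 0.0738, 0.12, 0.146, 0.082, 0.0541 and 0.0872. Without the pair that stood apart, E(spl)mdelta-HLH, E(spl)m3-HLH, N, mam, dan, bab2 and repo were at 0.0512, 0.149, 0.148, 0.288, 0.0905, 0.0617 and 0.208, again by edgeR adjusted p. The glial gene repo was lower, at 13.1 ± 0.348 against 20.5 ± 1.82 CPM (edgeR adjusted p = 0.0313), and lost its call without any 1 Canton S, knockout or RMCE-1 library (up to 0.151).

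Camera called 5 stress, metabolic and histone lists in RMCE-1 relative to Canton S, where RMCE-1 replicate 2 held 4170 CPM of Hsp70 and 9280 CPM of fat body transcripts. With an estimated correlation each of these lists was at an adjusted p of 0.99. Heat shock and chaperone genes lay higher (1 of 17 called, 1 adjusted over the list alone; camera adjusted p = 0.00758). The called member was Hsp67Bc, a small heat shock family gene at 50.0 ± 1.92 against 15.2 ± 3.48 CPM (log2 fold change 1.72, SE 0.17, edgeR adjusted p = 0.00404). JNK and wound genes (2 of 18, 2 adjusted over the list alone; camera adjusted p = 0.0291) and immune effectors (2 of 20, 4 adjusted over the list alone; 0.00536) lay higher. So did histones, whose near-identical copies leave single values uncertain (0 of 111, 0 adjusted over the list alone; 0.00758). Oxidative phosphorylation genes lay lower (0 of 26 higher and 1 lower, 1 and 1 adjusted over the list alone; 0.00758). Without RMCE-1 replicate 2 these 5 lost their calls: JNK at camera adjusted p = 0.861, heat shock at 0.525, immune at 0.0644, oxidative phosphorylation at 0.318 and histones at 0.6. Without Canton S replicate 2 the JNK, immune, oxidative phosphorylation and histone lists were at 0.0561, 0.0775, 0.29 and 0.276. The JNK list was at 0.0996 without Canton S replicate 1 and 0.0569 without RMCE-2 replicate 1. Without the pair that stood apart, the JNK, heat shock and histone lists were at camera adjusted p = 0.98, 0.88 and 0.0556, and the immune and oxidative phosphorylation lists were still called.

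In all, edgeR called 671 of 11068 genes between RMCE-1 and Canton S, 315 higher and 356 lower (227 by at least 2-fold). With library totals alone as the scaling, higher genes made up 36.3% of calls against 46.9%. Without RMCE-1 replicate 1 the balance turned, to 545 higher and 248 lower (68.7% higher). The count was 160 without Canton S replicate 1, 215 without replicate 2, 317 and 314 without knockout replicates 1 and 2, 412 without RMCE-1 replicate 2, 141 with only the 4 libraries compared and 136 without the pair that stood apart. Camera called 6 lists, and 0 were called with an estimated correlation or by fry.

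RMCE-2 was compared with Canton S as the other reading of the design text. Tektin-C stood at 60.4 ± 4.49 CPM in RMCE-2 (log2 fold change 7.99, SE 0.55), sut2 at 26.8 ± 3.74 CPM (4.53, SE 0.17) and tut, which encodes an RNA-binding protein, at 13.4 ± 0.978 against 1.49 ± 0.128 CPM (3.17, SE 0.20). The edgeR adjusted p was 0.00285, 0.000346 and 0.00116. CG3984 was lower, at 0.293 ± 0.0197 CPM (-5.93, SE 0.42, edgeR adjusted p = 0.00143). The photoreceptor transcription factor gene salr rose from 45.5 ± 0.748 to 78.0 ± 4.25 CPM (0.78, SE 0.08, 0.00482) and Hsp67Bc from 15.2 ± 3.48 to 55.1 ± 7.11 CPM (1.86, SE 0.17, 0.00363). All 6 were called in every left-out-library fit and every other setting.

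**Figure D4:**
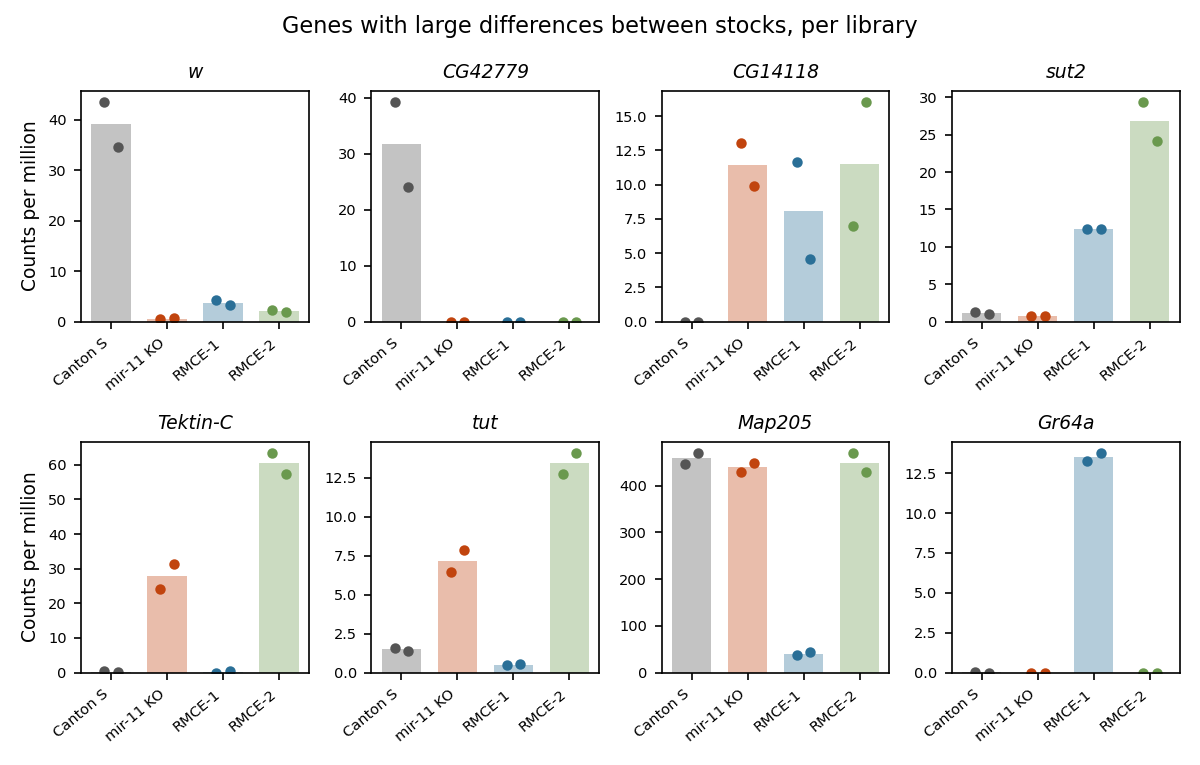
Levels of w, CG42779, CG14118, sut2, Tektin-C, tut, Map205 and Gr64a in CPM (vertical axes) by stock, with bars for the mean of 2 libraries and points for each library. Map205 stood at 40.5 CPM in RMCE-1 and at 439.5 to 459.5 CPM in the other stocks.

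Blood cell transcripts were lower in RMCE-2 than in Canton S, with 5 of 18 hemocyte markers lower and none higher (10 and 1 adjusted over the list alone; camera adjusted p = 2.66e-06, or 0.723 with an estimated correlation). PPO2, which encodes the prophenoloxidase of crystal cells, stood at 10.6 ± 3.88 against 108 ± 0.97 CPM (log2 fold change -3.32, SE 0.35, edgeR adjusted p = 0.00973). Pxn stood at 50.4 ± 1.63 against 152 ± 33.5 CPM (-1.59, SE 0.16, 0.00545), and the phagocytic receptor gene eater at 28.0 ± 0.274 against 72.7 ± 17.3 CPM (-1.37, SE 0.16, 0.00801). These calls were lost without either Canton S replicate for PPO2 (edgeR adjusted p up to 0.0553), without RMCE-2 replicate 1 for Pxn (0.056) and without either RMCE-2 replicate for eater (up to 0.071; 0.0536 with only the 4 libraries compared). Salivary gland markers lay lower as a list, with 0 of 14 members called singly or adjusted over the list alone (camera adjusted p = 7.7e-06, or 0.723 with an estimated correlation). The lack of single calls does not mean a small difference, since their sums were 214 and 217 CPM against 2400 and 1580 CPM. In RMCE-1 they were 201 and 4810 CPM, a spread that enters the fit shared by all stocks.

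Histone transcripts lay lower in RMCE-2 than in Canton S, with 3 of 111 called lower (30 adjusted over the list alone; camera adjusted p = 6.55e-13, or 0.723 with an estimated correlation), and the called members were near-identical His2B copies whose reads cannot be assigned with certainty. The 6 lists that follow were also at an adjusted p of 0.723 with an estimated correlation. Oxidative phosphorylation genes lay lower (1 of 26 called, 9 adjusted over the list alone; 2.66e-06), with the complex III subunit gene UQCR-14 at 66.0 ± 3.12 against 90.3 ± 2.0 CPM. E2F target and replication genes lay lower as a list (0 of 22 called, 8 lower and 1 higher adjusted over the list alone; 0.0126), without Canton S replicate 2 at 0.0791 and without RMCE-2 replicate 2 at 0.14. Heat shock and chaperone genes lay higher (1 of 17, 2 adjusted over the list alone; 0.00143), in the stock whose Hsp70 sums were 723 and 91.8 CPM. Immune effectors lay higher too (2 of 20, 4 adjusted over the list alone; 0.00404, or 0.0854 without Canton S replicate 2). Photoreceptor genes (2 of 23, 4 adjusted over the list alone; 0.0343) and Notch genes (0 of 18, 3 adjusted over the list alone; 0.00894) lay higher. The photoreceptor call was lost without Canton S replicate 1 (camera adjusted p = 0.126) or RMCE-2 replicate 2 (0.144), and the Notch call without Canton S replicate 1 (0.0733), and without the pair that stood apart they were at 0.112 and 0.0727. UQCR-14 (edgeR adjusted p = 0.0134) was not called without either Canton S replicate or RMCE-2 replicate 1 (up to 0.0831), with only the 4 libraries compared (0.0557) or without the pair that stood apart (0.0534). The His2B copies lost their calls without any 1 Canton S, knockout or RMCE-2 library (edgeR adjusted p up to 0.23). With library totals alone as the scaling they were at up to 0.0766, with only the 4 libraries compared at up to 0.12 and without the pair that stood apart at up to 0.151.

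In all, edgeR called 398 of 11068 genes between RMCE-2 and Canton S, 221 higher and 177 lower (165 by at least 2-fold), and DESeq2 called 662. Higher genes made up 55.5% of calls, against 43% without Canton S replicate 1 or the pair that stood apart. The edgeR count was 142 and 181 without Canton S replicates 1 and 2, 208 without either knockout replicate, 133 and 237 without RMCE-2 replicates 1 and 2, 187 with only the 4 libraries compared and 256 without the pair that stood apart. Camera called 9 lists, 15 without RMCE-1 replicate 1 or 2 and 16 with no filter on low counts, against 0 with an estimated correlation, and fry called the eye pigment list (fry adjusted p = 0.042).

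Few genes were called between RMCE-1 and the knockout stock, which does not show that these stocks are alike. Map205 stood at 40.5 ± 4.8 CPM in RMCE-1 against 439.5 ± 13.4 CPM (log2 fold change -3.44, SE 0.10, edgeR adjusted p = 4.89e-05). tut stood at 0.514 ± 0.0012 against 7.13 ± 1.01 CPM (-3.77, SE 0.23, 0.00242) and sut2 at 12.4 ± 0.0619 against 0.787 ± 0.0214 CPM (3.96, SE 0.18, 0.000577). These 3 were called in every left-out-library fit and every other setting. Gr64a had no read in the knockout libraries, and RMCE-1 was at least 160-fold higher (edgeR adjusted p = 0.0137), a call lost without knockout replicate 1 or 2 or RMCE-1 replicate 2 (up to 0.106) and without the pair that stood apart (0.0621). The lipid droplet gene sturkopf stood at 36.6 ± 0.373 against 93.5 ± 0.55 CPM (-1.35, SE 0.09, edgeR adjusted p = 0.00319), which was 0.0538 without knockout replicate 2. The w transcript was higher in RMCE-1 (2.72, SE 0.28, edgeR adjusted p = 0.0137), a call lost without knockout replicate 1 or 2 (up to 0.155) and with only the 4 libraries compared (0.133).

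Mitosis genes lay lower in RMCE-1 than in the knockout stock as a list (0 of 25 called, 0 adjusted over the list alone; camera adjusted p = 1.27e-05, or 0.732 with an estimated correlation), as did antennal disc markers (0 of 14, 4 lower adjusted over the list alone; 6.19e-05, or 0.732). With an estimated correlation the next 3 lists were at 0.732 too. Retinal determination genes (0 of 12, 1 lower adjusted over the list alone; 0.00355) and photoreceptor genes (0 of 23, 0 adjusted over the list alone; 0.0167) lay lower too. Ecdysone-response genes lay higher (1 of 20, 2 adjusted over the list alone; 0.01). The kinase gene Eip63E stood at 141 ± 4.45 against 108 ± 1.24 CPM. Detoxification genes (1 of 31, 2 adjusted over the list alone; camera adjusted p = 8.89e-06), heat shock genes (0 of 17; 0.000114), JNK and wound genes (0 of 18; 0.00355) and histones (0 of 111; 0.0223) lay higher. Oxidative phosphorylation genes lay lower (0 of 26; 0.000436), and these last 4 lists had 0 members called adjusted over the list alone. With an estimated correlation detoxification and heat shock genes were at an adjusted p of 0.732, JNK and oxidative phosphorylation genes at 0.761 and histones at 0.831. Without RMCE-1 replicate 2, the library with 4170 CPM of Hsp70, the detoxification, heat shock, JNK, histone and oxidative phosphorylation lists were not called (camera adjusted p = 0.663, 0.278, 0.817, 0.204 and 0.273), nor were photoreceptor genes (0.205). JNK and histone genes then lay on the lower side. Without the pair that stood apart the same 6 lists were at 0.706, 0.27, 0.731, 0.168, 0.253 and 0.183. Without knockout replicate 2 the photoreceptor and retinal lists were at 0.137 and 0.0763, and the ecdysone list was at 0.121 without RMCE-1 replicate 1. The histone list was at 0.0927 without knockout replicate 1, 0.122 with library totals alone as the scaling and 0.06 with no filter on low counts. Eip63E (edgeR adjusted p = 0.0492) lost its call without any 1 library except RMCE-1 replicate 1 (up to 0.485), with library totals alone (0.142), with no filter on low counts (0.0587), with only the 4 libraries compared (0.167) and without the pair that stood apart (0.244).

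In all, edgeR called 39 of 11068 genes between RMCE-1 and the knockout stock, 23 higher and 16 lower, and 999 at an unadjusted p under 0.05, and DESeq2 called 143. With library totals alone as the scaling, higher genes made up 40% of calls against 59%, whereas they made up 86.1% without RMCE-1 replicate 1 and 71.4% without the pair that stood apart. The edgeR count was 6 and 5 without knockout replicates 1 and 2, 259 without RMCE-1 replicate 1, 20 without replicate 2 and 25 with only the 4 libraries compared. Camera called 10 lists, or 16 without RMCE-1 replicate 1, and 0 with an estimated correlation or by fry.

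RMCE-2 differed from the knockout stock most clearly at sut2, at 26.8 ± 3.74 against 0.787 ± 0.0214 CPM (log2 fold change 5.07, SE 0.18, edgeR adjusted p = 0.000224). CG8785, at 32.1 ± 0.506 against 9.73 ± 0.236 CPM (1.72, SE 0.08, 0.000733), was higher and CG32373, at 1.66 ± 0.143 against 21.2 ± 0.0224 CPM (-3.67, SE 0.21, 0.00206), lower, and these 3 genes were called in every left-out-library fit and every other setting. The retinoid-binding protein gene pinta was lower (-1.84, SE 0.15, edgeR adjusted p = 0.00875; up to 0.0794 without knockout replicate 2 or RMCE-2 replicate 1). Ecdysone-response genes lay higher in RMCE-2, with 2 of 20 called (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.82e-08, or 0.403 with an estimated correlation; fry adjusted p = 0.048). Hr3 stood at 123 ± 6.69 against 26.9 ± 6.97 CPM (2.19, SE 0.21, edgeR adjusted p = 0.021) and Hr4 at 151 ± 24.5 against 58.5 ± 13.4 CPM (1.37, SE 0.18, 0.0414). The call of Hr3 was lost without knockout replicate 2 or either RMCE-2 replicate (edgeR adjusted p up to 0.103). That of Hr4 was lost without any 1 of the 8 libraries (up to 0.164), with only the 4 libraries compared (0.109) and without the pair that stood apart (0.105).

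Growth and cell cycle lists lay lower in RMCE-2 than in the knockout stock, each with 0 members called over all genes. Histones led (0 of 111 called or called adjusted over the list alone; camera adjusted p = 1e-25, or 0.606 with an estimated correlation). That list holds near-identical copies that may share reads, so its members are not 111 separate measures. With an estimated correlation the next 6 lists were not called either, at an adjusted p of 0.681 for the ribosomal proteins and 0.606 for the others. They were followed by oxidative phosphorylation (0 of 26; 1.28e-07), E2F targets (0 of 22; 0.00021) and ribosome biogenesis (0 of 24; 0.00021). Cytosolic ribosomal proteins (0 of 78; 0.000628) and mitosis (0 of 25; 0.0013) came next, each of these 5 with 0 members adjusted over the list alone, and then retinal determination (0 of 12, 2 adjusted over the list alone; 0.0238). Heat shock genes lay higher (0 of 17; camera adjusted p = 0.000211, or 0.606 with an estimated correlation). So did JNK and wound genes (0 of 18; 0.0284, or 0.674) and detoxification genes (1 of 31; 0.0218, or 0.681), with 0, 0 and 1 members adjusted over the list alone. Calls were lost without RMCE-2 replicate 1 for ribosomal proteins (camera adjusted p = 0.129), retinal genes (0.06), JNK (0.34) and detoxification (0.813). They were lost without RMCE-2 replicate 2 for mitosis and retinal genes (0.0717 each). Without knockout replicate 2 the retinal, JNK and detoxification lists were at 0.187, 0.0761 and 0.102. Without knockout replicate 1 JNK was at 0.0674, and without Canton S replicate 1 JNK and detoxification were at 0.055.

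Lists of markers of other cells lay on both sides between RMCE-2 and the knockout stock, none of them called with an estimated correlation (adjusted p of 0.62 for muscle and brain and 0.606 for the others). Hemocyte (0 of 18, 3 lower adjusted over the list alone; camera adjusted p = 0.00217) and salivary gland markers (0 of 14, 1 higher adjusted over the list alone; 0.00229) lay lower as lists. So did muscle markers (0 of 18, 1 higher and 1 lower adjusted over the list alone; 0.00999). Fat body (0 of 14, 0 adjusted over the list alone; 0.00679), larval cuticle and trachea (0 of 15, 2 higher and 1 lower adjusted over the list alone; 0.00999) and brain neuron markers (0 of 17, 1 higher adjusted over the list alone; 0.0106) lay higher. Without RMCE-2 replicate 2 salivary, muscle, fat body and brain markers were at camera adjusted p = 0.0732, 0.571, 0.0717 and 0.571. Without knockout replicate 2 fat body, cuticle and brain markers were at 0.0789, 0.0761 and 0.643.

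In all, edgeR called 64 of 11068 genes between RMCE-2 and the knockout stock, 37 higher and 27 lower, and 1459 at an unadjusted p under 0.05, and DESeq2 called 260. With the replicate number as a block edgeR called 9. The edgeR count was 36 and 35 without Canton S replicates 1 and 2, and 9 and 3 without knockout replicates 1 and 2. It was 99 and 102 without RMCE-1 replicates 1 and 2, 9 and 8 without RMCE-2 replicates 1 and 2, and 103 with only the 4 libraries compared. Camera called 17 lists, and 0 were called with an estimated correlation.

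Between RMCE-2 and RMCE-1, Map205 stood at 449 ± 29 against 40.5 ± 4.8 CPM (log2 fold change 3.47, SE 0.10, edgeR adjusted p = 4.64e-05) and tut at 13.4 ± 0.978 against 0.514 ± 0.0012 CPM (4.69, SE 0.23, 0.000813). CG32373 was lower in RMCE-2 (-4.25, SE 0.22, edgeR adjusted p = 0.000813), as was snoRNA:Psi28S-1837a (-4.21, SE 0.25, 0.00122). These 4 were called in every left-out-library fit and every other setting. Ecdysone-response genes lay higher in RMCE-2 (2 of 20 called, 10 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00223, or 0.7 with an estimated correlation). Hr3 stood at 123 ± 6.69 against 44.0 ± 8.24 CPM and Hr4 at 151 ± 24.5 against 62.8 ± 3.5 CPM (edgeR adjusted p = 0.0282 and 0.0281). Hr3 lost its call without either Canton S replicate, RMCE-1 replicate 2 or either RMCE-2 replicate (edgeR adjusted p up to 0.142). Hr4 lost its call without any 1 Canton S, RMCE-1 or RMCE-2 library (up to 0.127). With only the 4 libraries compared they were at edgeR adjusted p = 0.0788 and 0.0825 and without the pair that stood apart at 0.153 and 0.209.

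A few eye and antennal genes were called between RMCE-2 and RMCE-1. The receptor tyrosine kinase gene sev, needed for photoreceptor R7, stood at 258 ± 8.26 against 154 ± 7.62 CPM (log2 fold change 0.74, SE 0.09, edgeR adjusted p = 0.0169). salr stood at 78.0 ± 4.25 against 50.4 ± 0.957 CPM (0.63, SE 0.08, 0.0192). The photoreceptor list lay higher (2 of 23, 2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0153, or 0.851 with an estimated correlation). Antennal disc markers lay higher (2 of 14, 2 and 2 adjusted over the list alone; 0.0119, or 0.7 with an estimated correlation). ct stood at 128 ± 3.0 against 84.1 ± 5.04 CPM and bab2 at 125 ± 9.13 against 83.7 ± 3.24 CPM (both at edgeR adjusted p = 0.0169). Calls of sev, salr, ct and bab2 were lost at edgeR adjusted p up to 0.0768, 0.0879, 0.0845 and 0.0754. All 4 were lost without RMCE-2 replicate 2, all but bab2 without RMCE-2 replicate 1, salr without RMCE-1 replicate 2, and ct and bab2 without either knockout replicate. With only the 4 libraries compared the 4 genes were at edgeR adjusted p = 0.0872, 0.124, 0.134 and 0.152, and without the pair that stood apart sev, salr and bab2 were at 0.0735, 0.111 and 0.0915. The photoreceptor list was not called without RMCE-1 replicate 2 (camera adjusted p = 0.105) or RMCE-2 replicate 2 (0.122), nor the antennal list without RMCE-1 replicate 2 (0.105) or RMCE-2 replicate 1 (0.0536), and without the pair that stood apart they were at 0.0895 and 0.111.

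The histone list holds near-identical copies that may share reads, so its members are not 111 separate measures. It lay lower in RMCE-2 than in RMCE-1 (0 of 111 called, 69 adjusted over the list alone; camera adjusted p = 1.87e-31, or 0.7 with an estimated correlation). So did hemocyte markers (2 of 18, 5 adjusted over the list alone; 0.000317, or 0.888). PPO2 stood at 10.6 ± 3.88 against 73.7 ± 27.4 CPM and Pxn at 50.4 ± 1.63 against 114 ± 7.88 CPM. Ribosome biogenesis (0 of 24 called; camera adjusted p = 0.00569, or 0.851 with an estimated correlation), cytosolic ribosomal protein (0 of 78; 0.0138, or 0.888) and salivary gland lists (0 of 14; 0.0128, or 0.888) lay lower, each with 0 members adjusted over the list alone. E2F target (0 of 22; 0.0374, or 0.888) and muscle lists (0 of 18; 0.00569, or 0.888) lay lower too, with 1 higher and 1 lower E2F target and 1 lower muscle marker adjusted over the list alone. The gene of the synaptic active zone brp stood at 55.0 ± 1.99 against 35.03 ± 3.58 CPM. Brain neuron markers lay higher (1 of 17, 1 adjusted over the list alone; camera adjusted p = 0.00569, or 0.888 with an estimated correlation). So did glial markers (0 of 13, 2 adjusted over the list alone; 0.0238, or 0.7). Without RMCE-1 replicate 1 the lists of ribosome biogenesis, ribosomal proteins, E2F targets, muscle, brain and glia were at camera adjusted p = 0.219, 0.393, 0.361, 0.393, 0.0812 and 0.157. Without RMCE-2 replicate 2 those of E2F targets, muscle, salivary gland, brain and glia were at 0.295, 0.264, 0.14, 0.314 and 0.226. Ribosomal proteins were at 0.478 without RMCE-2 replicate 1. The salivary gland list was at 0.883 without RMCE-1 replicate 2, in which those transcripts summed to 4810 CPM, and at 0.926 without the pair that stood apart. With library totals alone as the scaling, E2F targets and ribosomal proteins were at 0.0865 and 0.0879. PPO2, Pxn and brp (edgeR adjusted p = 0.0281, 0.0252 and 0.0208) all lost their calls without either knockout or RMCE-2 replicate (up to 0.0998, 0.141 and 0.113). PPO2 also lost it without either Canton S replicate, Pxn without RMCE-1 replicate 2 and brp without Canton S replicate 2. With only the 4 libraries compared PPO2 and brp were at edgeR adjusted p = 0.209 and 0.162, and PPO2 was at 0.0645 without the pair that stood apart.

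In all, edgeR called 186 of 11068 genes between RMCE-2 and RMCE-1, 104 higher and 82 lower (79 by at least 2-fold), and DESeq2 called 428. With library totals alone as the scaling, higher genes made up 70.5% of calls against 55.9%. The share fell below that of lower genes without RMCE-1 replicate 1 (30.7%), with only the 4 libraries compared (29.4%) and without the pair that stood apart (44.1%). Without the 8 libraries in turn the edgeR count was 100 and 87 (Canton S replicates 1 and 2), 36 and 37 (knockout), 375 and 100 (RMCE-1), and 30 and 19 (RMCE-2). It was 17 with only the 4 libraries compared and 68 without the pair that stood apart. Camera called 12 lists, and 0 were called with an estimated correlation or by fry.

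Both RMCE stocks shared many differences from Canton S. Of the genes called against Canton S, 142 were higher and 102 lower in both, and sturkopf and tut were called in opposite directions. sut2 and CG32512 were higher in both RMCE stocks against both Canton S and the knockout stock, with sut2 at an edgeR adjusted p of at most 0.00064 and CG32512 at most 0.0499. CG32512 stood at 21.5 ± 1.27 CPM in RMCE-1 and 20.2 ± 0.585 CPM in RMCE-2, against 12.96 ± 0.0895 CPM in Canton S and 12.9 ± 1.04 CPM in the knockout stock, and each of its 4 calls was lost without either Canton S replicate. The CG32512 calls against the knockout stock were also lost without either knockout or RMCE-2 replicate or with library totals alone, and singly that of RMCE-1 without RMCE-1 replicate 2 and that of RMCE-2 with no filter on low counts (0.0525). So was that of RMCE-2 against Canton S without either RMCE-2 replicate. Its highest edgeR adjusted p without 1 library was 0.0669 and 0.0996 against Canton S and 0.419 and 0.327 against the knockout stock, for RMCE-1 and RMCE-2, and in other settings it was 0.0811, 0.0861, 0.136 and 0.07. The 3 stocks other than Canton S shared 116 higher and 84 lower genes against Canton S. CG42779 had no read in any of these 3, and lay at least 291-fold below Canton S in RMCE-1 and 331-fold in RMCE-2 (edgeR adjusted p = 0.0141 and 0.0148). The calls were lost with DESeq2 (adjusted p = 0.153 and 0.171), and the edgeR adjusted p was 0.0507 for RMCE-1 with only the 4 libraries compared and 0.0568 for RMCE-2 without its replicate 1. CG14118 had no read in Canton S and was at least 150-fold higher in the knockout stock, 112-fold in RMCE-1 and 159-fold in RMCE-2 (edgeR adjusted p = 0.0233, 0.0257 and 0.0261). Its calls were lost without any 1 Canton S or knockout library, and that of RMCE-2 without RMCE-2 replicate 1 (edgeR adjusted p up to 0.112, 0.107 and 0.105). Without the pair that stood apart they were at 0.0694, 0.0995 and 0.0816, and with only the 4 libraries compared those of RMCE-1 and RMCE-2 were at 0.083 and 0.0725.

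Sharing of this kind is partly built into comparisons with the same 2 control libraries. Unchanged groups simulated against the Canton S libraries in 50 draws shared 0.3 genes on average and 2 at most, against 244 observed, and independent lists would share 6.29 higher and 5.69 lower genes. The draws held no difference between any stocks, so few calls and little sharing were built in. They cannot show how much stocks with separate differences would share through the same controls, here or for the knockout stock below. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.681 against 0.479 simulated, and the covariance 0.492 against 0.116, a difference of 0.375. Fold changes had the same sign in 71.8% of genes, against 66.2% simulated. Against the knockout stock 6 higher and 3 lower genes were shared (9 against 0.28 on average and 4 at most in the simulation; 0.0769 and 0.039 in independent lists). The correlation was 0.547 against 0.494, the covariance 0.279 against 0.124 (difference 0.156), and 61.2% against 66.4% of genes had the same sign. With each RMCE stock set against a different library of the reference stock, a split added after the data were seen, edgeR called 72 and 61 genes in both against Canton S and 1 and 1 against the knockout stock. The covariance was then 0.265 and 0.289, and 0.196 and 0.223. This split left 1 control library on each side, assumed to vary like the other stocks, and part of the excess without it may come from the shared controls. The overlap against Canton S was 77 and 111 without Canton S replicates 1 and 2, 123 and 121 without knockout replicates 1 and 2, and 96 and 156 without RMCE-2 replicates 1 and 2. It was 59 with only the groups compared and 84 without the pair that stood apart. The overlap against the knockout stock was 5 without either Canton S replicate, 1 without either knockout replicate, 22 and 4 without RMCE-1 replicates 1 and 2, and 2 without either RMCE-2 replicate.

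Several lists were called by camera in none of the 6 comparisons: cell death (19 members tested), EGFR and Ras signalling (22), Hedgehog, Dpp, Wingless and JAK-STAT signalling (19), glycolysis and lactate dehydrogenase (11), eye pigment genes (10), and markers of testis (6), ovary (5) and gut (8). Single members of these lists were called all the same. Dronc was lower than in Canton S in the 3 other stocks (log2 fold change -0.76, -0.61 and -0.44; edgeR adjusted p = 0.00438, 0.00902 and 0.0304). AGO3, an Argonaute gene of the piRNA pathway held in the ovary list, was higher in all 3 of them (1.27, 1.36 and 1.01; 0.0175, 0.0139 and 0.0444). The Dronc calls were lost without knockout replicate 1 or 2 in the knockout comparison (edgeR adjusted p up to 0.0617), without either Canton S replicate for RMCE-1 (up to 0.0574) and without any Canton S or knockout library or RMCE-2 replicate 1 for RMCE-2 (up to 0.152). The AGO3 calls were lost without any Canton S or knockout library in the knockout comparison (up to 0.143), without either Canton S replicate for RMCE-1 (up to 0.0777) and without any Canton S, knockout or RMCE-2 library for RMCE-2 (up to 0.209). Without the pair that stood apart, Dronc was at edgeR adjusted p = 0.0797 and 0.104 in RMCE-1 and RMCE-2, and AGO3 at 0.054, 0.0695 and 0.0974 in the 3 stocks. With only the 4 libraries compared Dronc was at edgeR adjusted p = 0.102 in RMCE-2 and AGO3 at 0.0796 and 0.126 in RMCE-1 and RMCE-2. Of the Y-linked list, none of the 6 matched genes passed the filter on low counts.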

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

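The tests of explanations in this part were chosen after the results were seen; the edgeR comparisons of stocks and the camera tests of lists were planned.

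The effects of the RMCE stocks against Canton S differed at 186 genes by the direct edgeR test of RMCE-2 against RMCE-1. Among them sturkopf and tut were called in opposite directions against Canton S. sturkopf had log2 fold changes of -0.43 in RMCE-1 and 1.13 in RMCE-2, a difference of 1.57 (SE 0.09, edgeR adjusted p = 0.00122), and tut had -1.52 and 3.17, a difference of 4.69 (SE 0.23, edgeR adjusted p = 0.000813). The mean log2 fold change of the ecdysone-response list differed by 0.359 between RMCE-2 and RMCE-1 (camera adjusted p = 0.00223, or 0.7 with an estimated correlation).

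Ecdysone-response genes stood higher in Canton S and RMCE-2 than in the knockout stock and RMCE-1. Salivary gland cells as the whole source are argued against, since the higher RMCE-2 salivary sum was 0.381 times the lower knockout sum, the opposite order. Fat body cells stay open: the fat body sum of RMCE-1 replicate 2 was 3.93 times the highest Canton S or RMCE-2 library, against such a source there, while the other 3 knockout and RMCE-1 libraries lay at 164 to 383 CPM, lower than Canton S and RMCE-2. Photoreceptor genes, which younger discs would hold less of, were not called as a list between the knockout stock and Canton S (3 of 23 called higher and 0 lower; camera adjusted p = 0.22). This does not decide on an age difference. The list was not called between RMCE-1 and Canton S either. It was higher in RMCE-2 than in RMCE-1 (camera adjusted p = 0.0153, or 0.851 with an estimated correlation), in the direction that an age difference would give. That call was lost without RMCE-1 replicate 2 or RMCE-2 replicate 2. Between RMCE-1 and the knockout stock the order was the opposite of what an age difference would give. There camera called the ecdysone list higher and the photoreceptor list lower in RMCE-1, neither of them with an estimated correlation. The photoreceptor call was lost without RMCE-1 replicate 2 or knockout replicate 2, and the ecdysone call without RMCE-1 replicate 1. The age at dissection, not given in the sources used here, thus stays open, as do the stocks' genotypes, which are confounded with their cultures and untested.

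Heat shock genes were high in 1 RMCE-1 library and, less so, in both RMCE-2 libraries. The genotype of RMCE-1 is argued against as the whole source, since the summed Hsp70 CPM of its replicates differed 207-fold. A larger amount of fat body RNA is argued against for RMCE-2 replicate 1, whose fat body sum was 0.521 times the higher Canton S sum. The ratio cannot tell whether fat body cells there held more Hsp70 each. Fat body cells may contribute in RMCE-2 replicate 2 (2.15 times that sum) and RMCE-1 replicate 2 (8.44 times the highest library without raised Hsp70), where dissection, handling and other cells cannot be told apart because no library isolates them. The genotype of RMCE-2, with Hsp70 raised in both libraries, was not tested as a source.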

How the results depend on the processing

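The fits without structural RNA genes and without Canton S replicate 1 and RMCE-1 replicate 2, the filter settings for named genes and the split of control libraries were chosen after the data were seen; the rest were planned. Of 218 called results of named genes, 54 kept their call in every fit without 1 library and 46 in every setting that tested them. Over all settings, 3023 values of called named genes and of E2f1, Cbl, mir-998 and w kept their direction and side of the threshold, 996 kept only the direction, 5 passed the threshold newly and 3 reversed. Counts of genes are in the order knockout stock, RMCE-1 and RMCE-2 against Canton S, RMCE-1 and RMCE-2 against the knockout stock, and RMCE-2 against RMCE-1. They were 526, 671, 398, 39, 64 and 186, and genes shared by the RMCE stocks were 244 against Canton S and 9 against the knockout stock. DESeq2 scaling in edgeR, library totals, no filter, the filter of 50 counts and leaving out structural RNA kept every count of genes within 1.5 times. DESeq2 gave 662 for RMCE-2 against Canton S, 143, 260 and 428 for the last 3 comparisons, and 35 shared against the knockout stock. With only the groups compared the counts were 1139, 141, 187, 25, 103 and 17, and 59 and 3 shared. Without Canton S replicate 1 and RMCE-1 replicate 2 they were 341, 136, 256, 100 for RMCE-2 against the knockout stock and 68 for RMCE-2 against RMCE-1, and 84 shared against Canton S. Leaving out 1 library gave 65 to 768, 160 to 793, 133 to 588, 5 to 259, 3 to 102 and 19 to 375 genes, and 77 to 264 and 1 to 22 shared. Fewer residual degrees of freedom are part of those fits, and the cause of single losses was not tested. With the replicate number as a block the counts were 318, 338, 253, 16, 9 and 55, and 149 and 2 shared. That block also ended 83 calls of named genes, which the passages above do not list singly. With each RMCE stock against a different control library 72 and 61 genes were shared against Canton S and 1 and 1 against the knockout stock. Replicate differences correlated across genes at 0.322 between Canton S and the knockout stock, so these stocks shared part of a replicate pattern. The other pairs of stocks were at -0.182, -0.21, -0.158, -0.37 and -0.056, so the replicate numbers showed no pairing common to all stocks.

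Lists called by camera were 8, 6, 9, 10, 17 and 12, and 0 in all 6 comparisons with an estimated correlation. They were 2, 0, 1, 0, 1 and 0 by fry, 16 for RMCE-2 against Canton S with no filter, and 5 to 9, 5 to 8, 9 to 15, 9 to 16, 12 to 17 and 8 to 15 without 1 library. The log2 difference of Cbl between the knockout stock and Canton S, 0.03, ran from -0.0228 without Canton S replicate 2 (-0.0188 without knockout replicate 2) to 0.0700 without knockout replicate 1. That of mir-998 between RMCE-1 and Canton S, -0.15, ran from -0.359 to 0.0857, without Canton S replicates 1 and 2. The fold changes of rpr, hid, grim and skl, counted apart from these, changed sign in 39 of 396 fits and were called in 2, so none is given. Tests of microRNA seed matches were not run. Depth limits the levels of mir-998, near 1 CPM, and of mir-11, with 0 to 2 reads per library.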

Other observations

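The test of chromosome position in this part and its follow-up tests were chosen after the results were seen.

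Large differences between stocks were also found at genes of other functions. The kinetochore gene Nnf1b rose from 0.524 ± 0.323 CPM in Canton S to 6.47 ± 0.941 CPM in RMCE-2 (edgeR adjusted p = 0.00886, or 0.0519 without RMCE-2 replicate 1). Hsc70-2, a chaperone gene, stood at 36.8 ± 0.404 CPM in RMCE-1 against 1.17 ± 1.28 CPM in Canton S and 0.310 ± 0.113 CPM in RMCE-2 (edgeR adjusted p = 0.0193 and 0.0267). The first call was lost without either knockout replicate or RMCE-1 replicate 2 (up to 0.062) and with only the 4 libraries compared (0.16). The second was lost without either knockout or RMCE-2 replicate or RMCE-1 replicate 2 (up to 0.161) and with no filter on low counts (0.0505). Dscam4, of the Dscam family of neuronal cell adhesion genes, stood at 115 ± 1.27 CPM in RMCE-2 against 8.90 ± 1.92 CPM in RMCE-1 (edgeR adjusted p = 0.0319). It lost its call without any 1 library but the Canton S ones (up to 0.159) and with no filter on low counts (0.0564). The cytochrome P450 gene Cyp6a17 stood at 30.1 ± 7.53 CPM in Canton S, 0.193 ± 0.105 CPM in the knockout stock, 60.3 ± 32.2 CPM in RMCE-1 and 47.2 ± 18.4 CPM in RMCE-2. It was called lower in the knockout stock than in Canton S (log2 fold change -7.20, SE 0.81, edgeR adjusted p = 0.0133), a call lost without Canton S replicate 2 or either knockout replicate (up to 0.117).

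Calls between RMCE-2 and the knockout stock lay near the edited locus more often than other genes tested. Within 5 Mb of E2f1 on 3R lay 14 of 59 called genes with a position (23.7%), against 896 of 10557 tested genes (8.49%). The one-sided Fisher exact p was 0.000324, or 0.00194 after Benjamini-Hochberg adjustment over 6 comparisons. Among genes of 3R alone, which held 26 of the 59, it was 0.0438, or 0.263 adjusted, so nearness to the locus was not told apart from an excess on the whole arm. In RMCE-1 against the knockout stock the window held 0 of 38 called genes. There 3L, an arm without the locus, held 15 of the 38 (39.5%, against 19.9% of tested genes). Between RMCE-2 and RMCE-1, 3L held 54 called genes (31.4%). An excess of calls on an arm was thus not limited to the arm of the locus, and the shares on 3L were not tested. A large change of E2f1 itself is argued against by a 95% interval of -0.405 to -0.0815 for its log2 difference. A stretch of chromosome that differs between the stocks may account for it and stays open. A stretch that RMCE-2 shares with Canton S was not told apart from none, since 64.3% of the called genes in the window were also called between the knockout stock and Canton S with RMCE-2 on the Canton S side, against 62.2% of those outside (Fisher exact p = 1). By sign alone RMCE-2 lay on that side in 13 of 14 and 41 of 45 genes, in comparisons that share the knockout libraries. With the replicate number as a block, 1 of 9 calls between RMCE-2 and the knockout stock lay in the window (one-sided Fisher exact p = 0.55). The count in the window was 1 of 9 calls without knockout replicate 1, 0 of 3 without knockout replicate 2, 2 of 9 and 2 of 8 without RMCE-2 replicates 1 and 2 (one-sided Fisher exact p = 0.55, 1, 0.174 and 0.143).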
